A study of Homo sapiens with 3 samples.

How the data were processed

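The series measured HOMEZ binding by ChIP-seq in MCF-7 cells, with 2 HOMEZ ChIP replicates and 1 input. The labels state fixation with 1% formaldehyde, sonication, an antibody against HOMEZ and sequencing with either single-end or paired-end reads, without saying which library had which. The submitters' processing notes name bcl2fastq 2.17, Trimmomatic 0.33, Bowtie 1.1.2 and MACS2 2.1.0, without their options. Each ChIP replicate had its own deposited peak list, so peaks were called per sample and not on pooled reads. A file of the input itself was not analysed here.

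For each peak, the fold enrichment at the summit over the caller's background was taken as the authors deposited it. The −log10 p-value and −log10 q-value per peak were likewise the authors' values. The deposited score lay within 1 of 10 times the −log10 p-value, rounded down, in all 3187 and 5695 listed summits, and was not used further. The smallest −log10 p-value was 2.31 in replicate 1 and 2.32 in replicate 2, just above the value for 0.005. The lists thus stop at a p-value of 0.005, and hold many peaks with q above 0.05. Fold and significance served to describe, rank and filter peaks within their list, and fold was compared between shared and other peaks of a list. Between the lists, fold was correlated over shared peaks, and the pile-ups solved from fold and p-value, as described below, were compared after correction for depth. Where a region had several summits, the strongest was kept, which left out 32 summits in replicate 1 and 55 in replicate 2.

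The processing notes name the builds hg38, hg19 and GRCh37 without a role. Contig names that exist only in GRCh38 appear in both lists, so coordinates are given as GRCh38, 1-based. Genes came from a RefSeq table of GRCh38.p14 with 20037 protein-coding genes on the chromosomes, which gives the start and end of each gene but neither strand nor exons. The test planned at transcription start sites was therefore made within 1000 bp of either gene boundary, and the exon, UTR and intron classes became inside or outside a gene. No genome sequence was used here, so the planned motif tests, backgrounds matched on GC content and exclusion of assembly gaps were not run. Of 1795 fixed list members, 1794 were found in the gene table.

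Depth is not written in the peak lists. The caller's fold is a ratio of (pile-up + 1) to (background + 1) and its p-value comes from a Poisson distribution, so the whole-number pile-up and the background were solved for each peak with 1 scale factor per list. All summits, 100% in each list, were matched within 0.0005 on the −log10 p scale. The scale factors correspond to 1.01 and 1.06 times as many ChIP as control reads in replicates 1 and 2. In 257 shared peaks with summits within 10 bp, 176 had backgrounds within 0.01 of a whole number in both lists and 157 of those were equal within 0.01, as a shared control gives. That this control was the input is inferred and not stated in the labels. Pile-ups ranged from 5 to 159 reads in replicate 1 and from 5 to 143 in replicate 2, which sets the precision of each fold. PCR duplicates cannot be recognised in peak lists, so intervals cover counting error only.

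The main tests, the samples in each and the gene lists were chosen before the data were examined, apart from the chromosome densities, the noncoding classes, the pile-up tests and the gene body tests, which came afterwards. Which alternatives were chosen afterwards is stated with their values in the closing section. Peaks were shared where they overlapped by at least 1 bp. Overlap was tested one-sided with 100000 random placements of replicate 1 peaks on their own chromosomes, and position relative to genes two-sided with 10000 placements of the shared summits. Chromosome length was taken as the end of the last annotated gene or peak. Shares were compared with Fisher's exact test, medians and correlations with 100000 permutations, and pile-ups with exact binomial tests, and p-values were adjusted by the Benjamini-Hochberg method within each family. The 31 fixed gene lists covered pathways, cell type markers, complexes and gene families, and were tested with Fisher's exact test against all other protein-coding genes. In gene bodies they were compared with genes matched in 50 length bins.

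The peaks named in the text followed a fixed rule. It took the 25 shared peaks with the best mean rank of −log10 p, which include the best 5 lying over 1000 bp from any gene boundary, and the best 3 peaks of each replicate alone. It also took up to 4 members of each gene list with a shared peak at a boundary, and HOMEZ, ESR1, GATA3, FOXA1 and TFF1 whatever their value. MEN1, NCOA3, MED13, ZNF219, the members of lists named for peaks in the gene body, and genes named only in the closing section were chosen after their values were seen.

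The alternatives were stricter thresholds, equal list lengths, other overlap rules, other windows, other gene sets, other placements and each replicate alone. All computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The methods were tested on simulated data. Of 20 unrelated pairs of lists, 1 gave an overlap p under 0.05, and 100% of 500 planted shared peaks were found. Of 20 sets of random points, 1 gave a p under 0.05 for the share at gene boundaries. In 20 runs with random summits no gene list was called. A list of 36 genes was called in 3 of 20 runs with 2 planted members and in 20 of 20 runs with 3. Simulated pile-ups were recovered in 100% of 3155 and 5640 peaks.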

Results

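HOMEZ, a homeodomain transcription factor with leucine zipper motifs, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in MCF-7, an estrogen receptor positive human breast cancer cell line. The series held 3 samples: 2 replicates of HOMEZ ChIP and 1 input, which is sheared chromatin sequenced without the antibody. The authors called peaks in each replicate separately, and both peak lists were analysed here. The input was seen only through the background that the peak caller set beside each peak; the labels do not name the control of the peak calls, and it is read here as the input. Replicate 1 had 3155 peak regions covering 1126 kb, and replicate 2 had 5640 covering 2051 kb. Median peak width was 330 bp in replicate 1 and 336 bp in replicate 2. Median fold enrichment over the caller's background was 3.96 (interquartile range 3.22 to 4.96) in replicate 1 and 3.78 (3.06 to 4.73) in replicate 2. Of these peaks, 1593 (50.5%) had q of at most 0.05 in replicate 1 and 3228 (57.2%) in replicate 2. The read pile-up at the summit, recovered from the deposited fold and p-values, had a median of 12 reads in both replicates, with an interquartile range of 9 to 16, and the median background was 2.0 reads. The median peak therefore rested on few reads. The ChIP library of replicate 2 was 1.05 times as deep as that of replicate 1. Nothing in the labels says that the replicates came from separate cultures, so differences between these samples may be technical, and no p-value here measures the spread between independent cultures.

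The first question was whether both replicates marked the same sites. The strongest sites were found in both, among them HBB, which encodes beta-globin, with 50.2-fold enrichment in replicate 1 and 36.0-fold in replicate 2, and PBXIP1, a partner of PBX homeodomain proteins, with 25.4-fold and 24.5-fold. HOMEZ itself carried a peak in both replicates, at 17.4-fold and 13.2-fold. The peaks at these genes were over 1000 bp wide in both lists. Cloned DNA carried into both ChIP libraries stayed open as their source, as described in the closing section. In all, 1515 of the 3155 replicate 1 peaks (48.0%) overlapped a replicate 2 peak by at least 1 bp, and 1512 of the 5640 replicate 2 peaks (26.8%) overlapped a replicate 1 peak. Random placement of the replicate 1 peaks on their own chromosomes gave 4.55 ± 2.13 overlapping peaks (mean ± SD of 100000 placements, one-sided permutation p = 1e-05, the smallest that these placements can give). Both lists came from the same cell line and probably the same control. Anything besides HOMEZ binding that they have in common can raise overlap above uniform placement. The p-value therefore tests repeatability of the calls and not binding. The summits of the 1512 shared pairs lay a median of 34 bp apart, and 88.7% lay within 100 bp.

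The share found again rose with peak strength. Among replicate 1 peaks with −log10 q of at least 10, 173 of 176 (98.3%, exact binomial 95% interval 95.1 to 99.6) were found in replicate 2, against 465 of 1562 (29.8%, 27.5 to 32.1) among peaks with q above 0.05. In replicate 2 the shares were 248 of 259 (95.8%, 92.5 to 97.9) and 329 of 2412 (13.6%, 12.3 to 15.1). Intervals here and below cover counting error only.

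**Figure D1:**
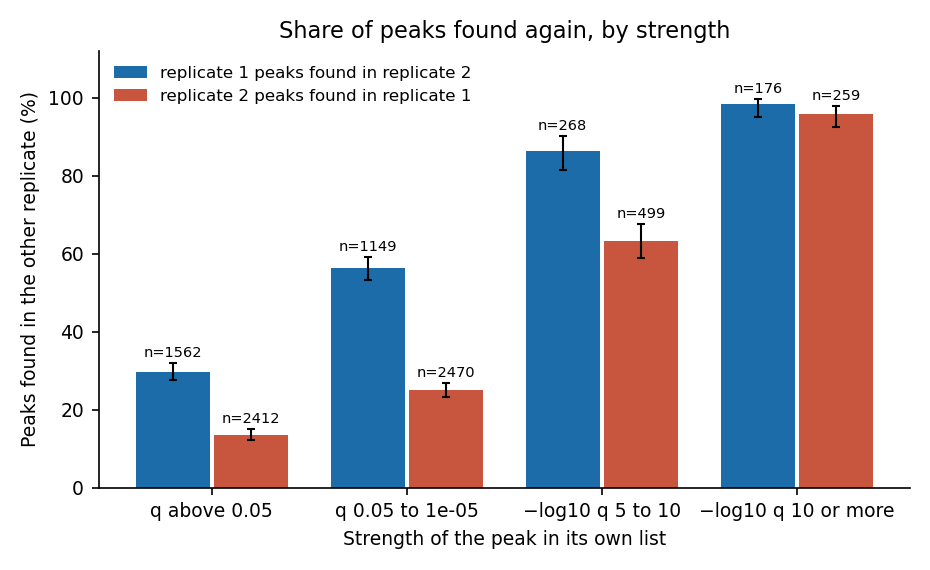
Percentage of HOMEZ peaks found in the other replicate, by the strength of the peak in its own list, for replicate 1 (blue) and replicate 2 (red). Bars are percentages of the n peaks printed above them and error bars are exact binomial 95% intervals; the share was 98.3% and 95.8% in the strongest band and 29.8% and 13.6% in the weakest.

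Fold enrichment ranked the shared sites alike in the 2 replicates. HBB stood highest in both lists, and next came PBXIP1 at 25.4-fold and 24.5-fold. Across the 1512 shared peaks, log2 fold enrichment gave Pearson's r = 0.733 and Spearman's rho = 0.680 (two-sided permutation p = 1e-05 for each, the smallest that 100000 resamples can give). This correlation was across peaks within 2 samples, and peaks are not independent replicates. Both folds at a site were probably taken over the same control, and a common background can raise the correlation by itself. How much of it came from the ChIP reads alone was not tested. No difference in read pile-up between the replicates was detected at a shared peak: 0 of 1512 passed a two-sided exact binomial test with Benjamini-Hochberg adjustment, and 28 (1.85%), HBB among them, had an unadjusted p under 0.05. Peaks listed in both replicates were selected for pile-ups high enough in both. After correction for depth, 865 of the 1512 (57.2%) had the higher pile-up in replicate 2, and the median ratio of replicate 2 to replicate 1 was 1.04. The smallest peak width was 278 bp in replicate 1 and 286 bp in replicate 2. The lowest background was 2.71 reads per kb of that width in both, as if reads were extended to those lengths. Longer extension raises pile-ups, and the ratio was not corrected for it. Replicate 2 listed 1.79 times as many peaks, and no other replicate pair was present to compare with this one, so the replicates were kept as 2 samples.

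**Figure D2:**
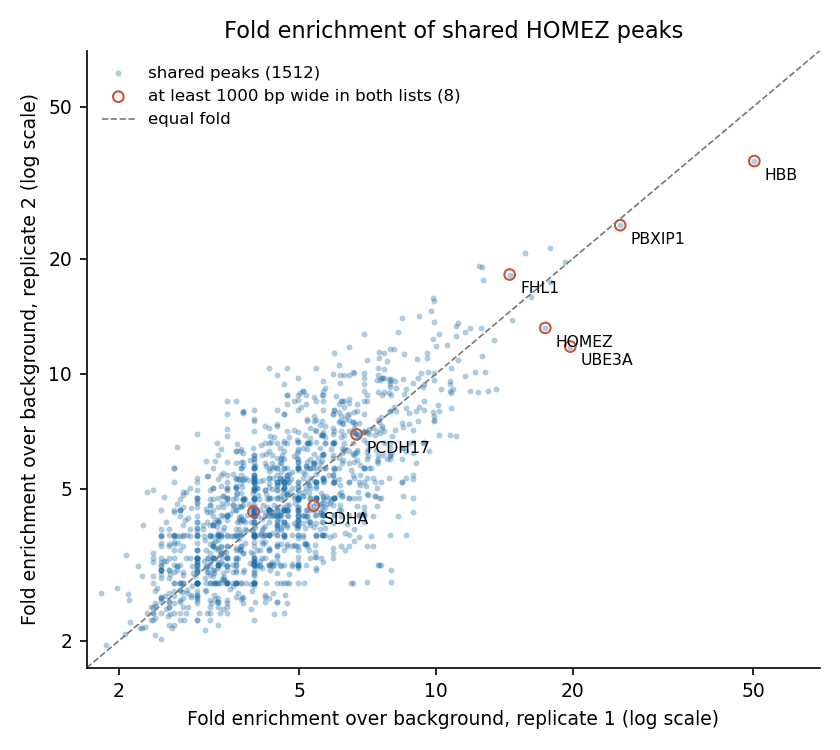
Fold enrichment over the caller's background in replicate 1 (x axis, log scale) and replicate 2 (y axis, log scale) for the 1512 shared HOMEZ peaks, each point 1 peak and the dashed line equal fold. Red circles mark the 8 peaks of at least 1000 bp in both lists, and HBB stands farthest out at 50.2-fold and 36.0-fold; the circle without a name is the weaker PBXIP1 peak.

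The 25 strongest shared peaks lay mostly away from gene ends. Of these, 15 lay inside a protein-coding gene and 10 outside, and only HBB and PBXIP1 had the summit within 1000 bp of a gene boundary. The HBB peak spanned 5224758 to 5226318 of chromosome 11 in replicate 1 (GRCh38), with its replicate 2 summit 78 bp from the gene's boundary, and held 88 and 67 reads at the summit. Its background, 0.754 and 0.776 reads, was the lowest of each list, a value that 201 replicate 1 and 305 replicate 2 peaks had alike (within 0.001), so its fold was taken over a minimum of the whole list and not over the input at the site. The stronger PBXIP1 peak spanned 154955950 to 154957481 of chromosome 1, with 94 and 92 reads. The HOMEZ peak spanned 23275471 to 23277192 of chromosome 14, inside the gene that runs from 23272422 to 23286132, with 41 reads in each replicate. These 3 peaks, and that in FHL1, which encodes a LIM domain protein (chromosome X, 136206281 to 136207332, 14.5-fold and 18.2-fold), were over 1000 bp wide in both lists, whereas the median peak was near 330 bp.

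**Figure D3:**
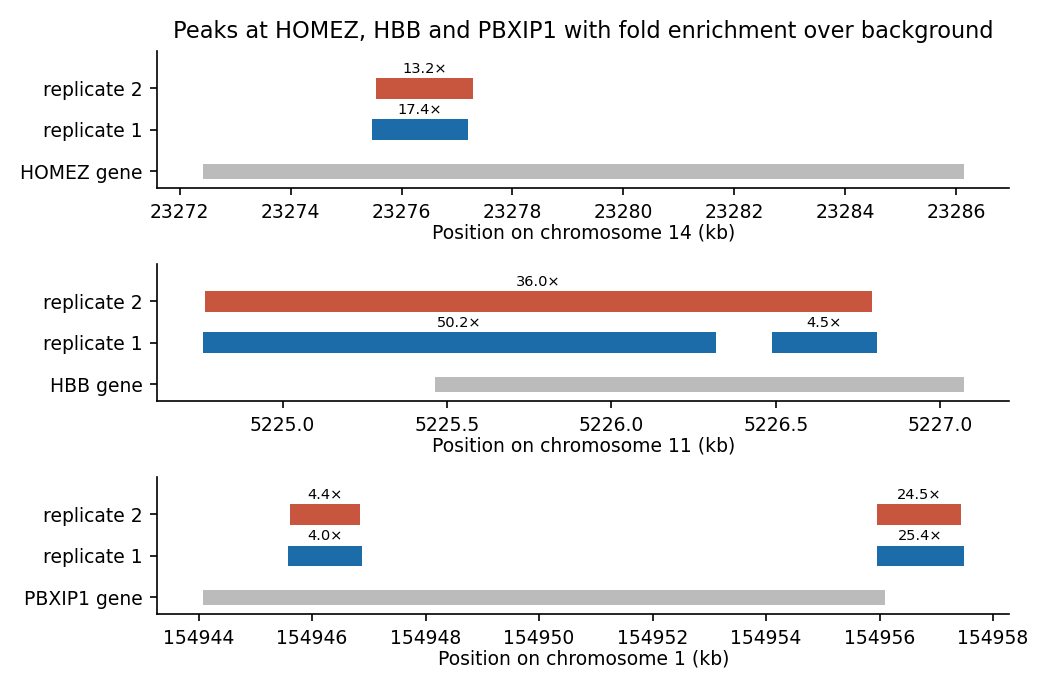
Peaks of replicate 1 (blue) and replicate 2 (red) at the HOMEZ, HBB and PBXIP1 genes (grey), to scale within each panel, with positions in kb on GRCh38. The number above each peak is its fold enrichment over the caller's background, such as 17.4 and 13.2 at HOMEZ.

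Inside genes, the strongest sites included RICTOR, a subunit of an mTOR complex (chromosome 5, 39028068 to 39028620, 8.45-fold and 7.25-fold), and MBNL1, a splicing regulator (chromosome 3, 152311761 to 152312293, 11.1-fold and 13.3-fold). A peak inside both RPA3, a subunit of the single-stranded DNA binding protein RPA, and UMAD1 (chromosome 7, 7677590 to 7678179) had 12.6-fold and 19.0-fold enrichment. SDHA, a subunit of succinate dehydrogenase, held 2 of the 25 (chromosome 5, 261187 to 261794 and 262012 to 262505), with 6.27-fold and 8.46-fold at the first and 4.74-fold and 5.20-fold at the second. The background at the RICTOR peak was 12 and 13 reads, and at the SDHA peaks 11 and 18 reads in both replicates, against a median of 2.0 reads over all peaks. LRBA (15.7-fold and 20.6-fold), PCNX2 (13.4-fold and 12.3-fold), COBLL1 (11.6-fold and 12.9-fold), CAMTA1 (9.11-fold and 9.72-fold) and CCNYL1 (8.58-fold and 8.15-fold) each held 1 of the 25 in their gene bodies. So did SEMA3A, which encodes a secreted axon guidance protein (7.78-fold and 10.8-fold), EPHA7, an ephrin receptor (12.5-fold and 13.2-fold), and NEGR1, a neuronal adhesion protein (10.0-fold and 11.8-fold).

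The strongest site over 1000 bp from any gene boundary and outside genes lay on chromosome 8 from 110601575 to 110602141, with 17.8-fold and 21.3-fold enrichment, 626057 bp from the boundary of KCNV1, its nearest protein-coding gene. A peak on chromosome 13 from 18211744 to 18212354, nearest to TUBA3C, had the most reads of all shared peaks, 159 and 143, over a background of 27 and 28 reads, so that its fold was only 5.66 and 4.67. Peaks nearest to GNAT3 (11.1-fold and 12.5-fold), SLITRK6 (17.8-fold and 17.4-fold), RGS18 (16.2-fold and 15.9-fold), CDH9 (9.08-fold and 10.9-fold) and CBLB (8.52-fold and 11.3-fold) lay from 27458 bp near GNAT3 to 874640 bp near CDH9 from a gene boundary. The remaining peak of this group lay on chromosome Y from 56763270 to 56763710, with 19.2-fold and 19.6-fold enrichment. Its background was the same minimum as that of HBB, and the nearest gene boundary lay 31137959 bp away. Whether these cells carry a chromosome Y, or reads from elsewhere were placed at this site, was not examined.

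The position of the shared peaks relative to protein-coding genes was compared with random placement. Shared summits lay within 1000 bp of a gene boundary at genes such as HBB, PBXIP1, MCM4, a subunit of the replicative helicase (7.08-fold and 6.10-fold), and MEN1, which encodes menin (4.94-fold and 3.94-fold). They numbered 66 of 1507 on the chromosomes (4.38%), 1.96 times the 2.23% ± 0.377 (mean ± SD) of random placement. A further 715 (47.4%) lay inside gene bodies, against 40.4% ± 1.27, and 726 (48.2%) lay outside genes, against 57.3% ± 1.26. All 3 differences gave a two-sided permutation p = 0.0002, the smallest that 10000 placements can give. A gene boundary was either end of the annotated gene, because strand was not part of the annotation used here. No excess at boundaries was detected for strong peaks. With −log10 q of at least 5 in both lists the share was 2.54% against 2.12% by chance (permutation p = 0.71). With at least 10 it was 1.59% (exact binomial 95% interval 0.193 to 5.62) against 2.13% (permutation p = 0.99). That interval includes the 4.38% of all shared peaks, so an equal excess was not excluded.

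**Figure D4:**
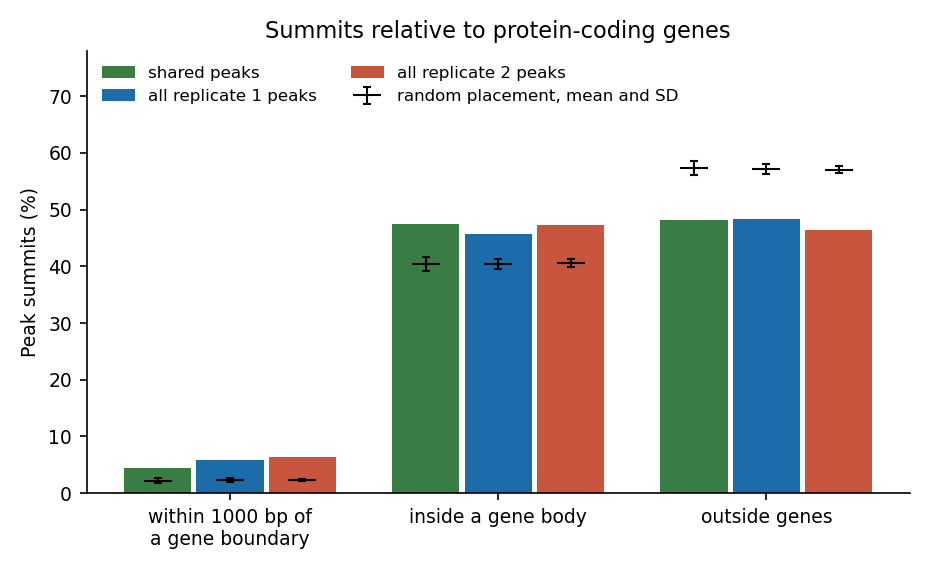
Percentage of peak summits within 1000 bp of a protein-coding gene boundary, inside a gene body and outside genes, for shared peaks (green) and all peaks of replicate 1 (blue) and replicate 2 (red). Black marks are the mean and SD of random placement; shared summits reached 4.38% at boundaries against 2.23%, and 48.2% outside genes against 57.3%.

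By annotated noncoding class, no count of shared summits departed from random placement after adjustment over 6 classes. A summit counted for a class if it lay in a gene of it or within 1000 bp of one. Long noncoding RNA genes held 247 summits (16.4% against 16.7% by chance, two-sided permutation p = 0.79). Pseudogenes held 36 (2.39% against 1.71%, permutation p = 0.065, adjusted 0.39). Small nucleolar RNA genes held 1, and tRNA, small nuclear RNA and microRNA genes held 0.

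Peaks found in both replicates were next set against peaks found in a single list. The strongest peak listed in replicate 1 only lay on chromosome 21 from 8208291 to 8208629 (9.41-fold), 378847 bp from the nearest gene, LOC102723475. Next came a peak on chromosome 2 (7.07-fold), 976095 bp from the nearest gene, TMEFF2, and a peak in NALCN, a sodium leak channel gene (8.29-fold). Those listed in replicate 2 only lay in CD109, which encodes a cell surface glycoprotein (chromosome 6, 73717651 to 73718080, 10.0-fold), and in FAM117B (6.97-fold). A further one lay on chromosome 2 (9.71-fold), 70660 bp from the nearest gene, LOC124906005. None of these differences was shown to be larger than counting error: 0 of 1640 replicate 1 and 0 of 4128 replicate 2 peaks had more reads than the most that the other list could hold without a call, by one-sided exact binomial tests with Benjamini-Hochberg adjustment. At an unadjusted p under 0.05 there were 114 (6.95%) and 272 (6.59%). The CD109 peak came nearest, with 31 reads against at most 6 (exact p = 3.95e-05, adjusted p = 0.163).

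Shared peaks were stronger than the others in their own list. The median fold was 4.46 against 3.63 in replicate 1 and 4.48 against 3.54 in replicate 2 (two-sided permutation p = 1e-05 in each, the smallest that 100000 resamples can give). Median pile-ups were 14 against 10 reads and 16 against 11 reads. A shared peak had to pass the caller's threshold in both lists, which favours stronger peaks. The difference in strength was thus built in by this selection, at least in part. Shared peaks lay at gene boundaries less often: 66 of 1510 (4.37%) against 117 of 1631 (7.17%) in replicate 1 (two-sided Fisher's exact p = 0.000781) and 66 of 1507 (4.38%) against 291 of 4116 (7.07%) in replicate 2 (Fisher's exact p = 0.000201, adjusted over both 0.000403). With only peaks of q at most 0.05 in both lists, that difference was −0.834 percentage points in replicate 1 (Fisher's exact p = 0.439) and −0.651 in replicate 2 (Fisher's exact p = 0.441), past the threshold in neither.

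Gene lists fixed in advance were tested for shared peaks at their boundaries, to learn which gene groups HOMEZ peaks mark. Of 20037 protein-coding genes, 79 (0.394%) had a shared summit within 1000 bp of a boundary and 662 (3.3%) had one in the gene or within 1000 bp of it. Among 36 cell cycle genes 2 had such a boundary peak: MCM4 (7.08-fold and 6.10-fold) and CDC25C, which encodes a phosphatase that activates mitotic entry (2.29-fold and 2.17-fold). Among 509 numbered zinc finger genes 5 had one: ZNF221 (5.45-fold and 8.50-fold), ZNF283 (5.95-fold and 5.20-fold), ZNF701 (4.0-fold and 4.31-fold), ZNF800 (4.62-fold and 3.46-fold) and ZNF219 (2.64-fold and 2.62-fold). Single members had one in DNA repair (PRKDC, at the same peak as its neighbour MCM4), the Wnt pathway (LGR5, 3.76-fold and 4.15-fold), replication-dependent histones (H2AC16, 3.40-fold and 2.91-fold) and proteasome subunits (PSMA7, 3.24-fold and 2.64-fold).

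None of the 31 lists passed a two-sided Fisher's exact test with Benjamini-Hochberg adjustment, and 1, cell cycle, had an unadjusted p under 0.05 (p = 0.00887, adjusted 0.275). By the same exact test, the zinc finger genes gave p = 0.0506 (adjusted 0.784), DNA repair p = 0.105, the Wnt pathway p = 0.0941, histones p = 0.239 and proteasome subunits p = 0.143. The other 25 lists had 0 members with a boundary peak. They were estrogen response, luminal transcription factors, epithelial structure, basal and mesenchymal markers, leukocyte markers, the TGF-beta, Notch, Hippo and PI3K and mTOR pathways, p53 targets, apoptosis, immediate early genes, hypoxia and glycolysis, autophagy and lysosome, and the circadian clock. The rest were subunits of NuRD, Polycomb and SWI/SNF, the ZHX and HOMEZ family, very highly transcribed genes, amplified regions, cytosolic ribosomal proteins, HOX clusters, olfactory receptors, mitochondrial complex I, splicing factors, and translation factors. With peaks of either replicate, an alternative chosen after seeing the data, 1 list passed: only 1 of 392 olfactory receptor genes (0.255%), OR2T10, had a boundary peak, against 2.72% of other genes (Fisher's exact p = 0.000655, adjusted 0.0203).

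In gene bodies, the TGF-beta pathway came nearest to the threshold, with 4 of 25 members against 1.19 for genes of matched length (two-sided permutation p = 0.056, adjusted 1). They were SKIL, a repressor of SMAD signalling (11.2-fold and 10.9-fold), SMAD2 (9.91-fold and 7.55-fold) and SMAD3 (5.45-fold and 4.66-fold), which carry the signal to the nucleus, and the coreceptor gene TGFBR3 (3.17-fold and 3.77-fold). Bodies of 3 of 21 Hippo pathway genes held a peak, in YAP1 (5.28-fold and 7.22-fold), MOB1A (4.81-fold and 3.17-fold) and TEAD1 (3.96-fold and 3.78-fold), against 1.27 by length (permutation p = 0.25). None of the 31 lists had an unadjusted p under 0.05 in gene bodies.

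The genes fixed in advance for the estrogen receptor program of MCF-7 had little or no listed HOMEZ signal. ESR1, which encodes estrogen receptor alpha, held 1 weak shared peak in its body (chromosome 6, 151898859 to 151899527), at 2.73-fold in replicate 1 and 2.27-fold in replicate 2, each with −log10 q of 0. GATA3, FOXA1 and TFF1 had no listed peak within the gene or 5 kb either side in either replicate. Of all protein-coding genes, only 3.3% had a shared summit in the gene or within 1000 bp of it. Most genes chosen in any way would therefore lack one, and no avoidance of these genes can be read from this. Because the lists hold only sites that passed the caller's threshold, weaker signal at these genes was not measured.

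Regions known to be amplified in MCF-7 were examined because extra copies raise read depth. NCOA3, a nuclear receptor coactivator gene on chromosome 20, held a shared peak of 3.17-fold and 4.95-fold, and MED13, a Mediator subunit gene on chromosome 17, held 1 of 2.77-fold and 4.02-fold. Within 100 kb of the 23 genes of the amplified regions lay 3 of the 1507 shared summits (0.199%, against 0.152% by chance, two-sided permutation p = 0.80). The median background at peaks in these regions was 2.61 reads in replicate 1 and 2.14 in replicate 2, against 2.0 elsewhere in each, a difference that was not tested. Counted over all peaks of replicate 2 alone, 16 of 5623 lay in these regions (0.285% against 0.152% by chance, permutation p = 0.033).

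Shared peaks were spread unevenly over the chromosomes. Their density was highest on chromosome 5, with 82.7 per 100 Mb, chromosome 12, with 76.6, and chromosome 4, with 69.9. It was lowest on chromosome Y, with 3.50, chromosome X, with 8.33, and chromosome 22, with 13.8. The gene-rich chromosomes 17 and 19 had 22.8 and 20.5. The chromosome Y value rested on 2 shared peaks, both over the minimum background of their list. Whether these cells carry a chromosome Y was not examined, so that value is not read as a density of HOMEZ sites. Chromosome Y was kept among the 24 chromosomes below. Density did not follow the number of protein-coding genes per Mb beyond chance across the 24 chromosomes (Pearson's r = −0.268, permutation p = 0.21; Spearman's rho = −0.276, permutation p = 0.19, adjusted over 8 such relations 0.507). Without chromosomes 17 and 19, the farthest from the median gene density, r was −0.0706 (permutation p = 0.75). For shared peaks with −log10 q of at least 5 in both lists rho was −0.483 (permutation p = 0.017, adjusted 0.136), and −0.372 without those chromosomes (permutation p = 0.087).

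**Figure D5:**
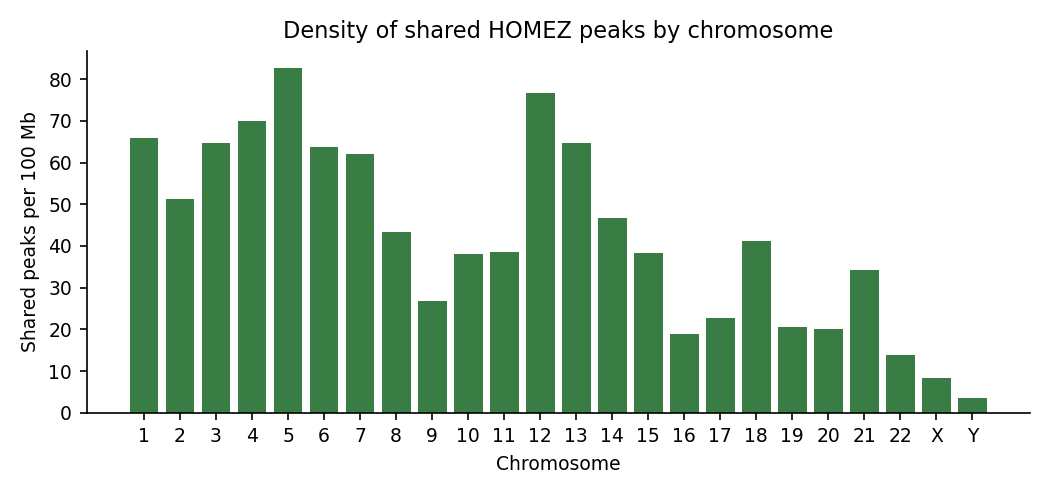
Shared HOMEZ peaks per 100 Mb of each chromosome (y axis), counted over the length up to its last annotated gene or peak. Bars reach from 3.50 on chromosome Y, which held 2 shared peaks, to 82.7 on chromosome 5.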

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

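All tests in this part except the thinning of replicate 2 to the depth of replicate 1 were chosen only after the result was seen. No biological explanation was tested here, because the series has a single ChIP group.

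Peaks appeared outside the chromosomes that the gene comparisons used: 5 peaks on contigs were shared by both replicates. Random placement of the replicate 1 contig peaks, up to the last peak of each contig, gave 0.0581 on average (one-sided permutation p = 0.0001, the smallest that 10000 placements can give). Their fold ran from 2.38 to 4.46 in replicate 1 and from 2.2 to 6.29 in replicate 2. Their background ran from 2.0 to 16.0 reads in replicate 1 and from 2.0 to 18.0 in replicate 2, and whether reads from repeated sequence were placed there, or at the SDHA peaks and the chromosome 13 site nearest to TUBA3C, was not tested. In all, 14 replicate 1 and 17 replicate 2 peaks lay on contigs.

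The 8 shared peaks of at least 1000 bp in both lists lay at HBB, PBXIP1 (2 peaks), HOMEZ, FHL1, UBE3A, SDHA and PCDH17, all in or at a gene, against 51.7% of all shared peaks. Their summits lay a median of 150 bp apart between replicates, against 23 bp in 191 shared peaks with at least 24 reads in both (permutation p = 4e-05). The reference was chosen by reads and not by width, and a wider peak leaves more room between summits. This difference can therefore follow from the choice of wide peaks alone. The comparison of edges below used the same reference, not matched on width. Extra copies with nothing else at work would leave the fold near 1. At the 8 peaks the median lower counting bound of the fold over the caller's background was 3.12, in the replicate where it was lower. The lowest single bound was 1.42, at the weaker PBXIP1 peak. Only peaks with enough fold were listed, so these bounds were raised by selection. They argue against extra copies without enrichment, but not against copies that helped a peak pass the caller's threshold over its background. That background was at percentile 50.4 of shared peaks by the median of the 8, but at percentile 94.1 or above at SDHA, PCDH17 and the weaker PBXIP1 peak in both replicates, where extra copies may still add to the signal. Cloned DNA with fixed ends stayed open as a candidate explanation: the outer edges, of peaks joined over gaps of up to 500 bp, moved by a median of 65.2 bp between lists against 32.0 bp elsewhere (permutation p = 0.02), but by only 22.0 and 31.0 bp at PBXIP1, and joining took HBB from 240.5 to 11.5 bp and FHL1 from 12.5 to 224.5 bp, so that the answer at HBB and FHL1 rested on the joining rule.

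Replicate 2 had 1.79 times as many peaks as replicate 1, among them the peak in CD109 (10.0-fold) that replicate 1 did not list. The tables argue against greater depth as the cause, since after thinning to the depth of replicate 1 a mean of 5430 replicate 2 peaks (95% of draws 5407 to 5453) still passed by summit height, against 3155. Weak calls alone do not account for it either, since at −log10 p of at least 10 there were 608 against 413 peaks, a ratio of 1.47 (exact 95% interval 1.30 to 1.67). Stronger enrichment at all sites in replicate 2 stayed open: the depth-corrected pile-up ratio had a median of 1.14 (bootstrap 95% interval 1.11 to 1.17) over 588 shared peaks that strong in either list, and of 1.06 (1.03 to 1.1) over the 285 that strong in both, while a factor of 1.13 would be needed. Because the answer changed with how the peaks were picked, stronger enrichment and another cause of the longer list cannot be told apart. The pile-up ratios were also not corrected for read extension, which appeared longer in replicate 2.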

How the results depend on the processing

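All alternatives for the differences between shared and other peaks, the density correlation, the share outside genes and the 25 strongest peaks were chosen only after the results were seen, as were, for every result, q of at most 0.05 in both lists, peaks of either replicate, gene bodies, leaving out wide peaks and placement outside long gene-free stretches. Of 133 values under alternatives, 114 kept their direction and their side of the threshold. These 114 include the counts of the 25 strongest peaks kept, which had no test. The share of replicate 1 peaks found in replicate 2 ran from 37.1% to 71.6%, and the rank correlation of shared peaks from 0.650 to 0.784. The share outside genes ran from 34.6% to 49.3%, always under its chance level. Of the 25 strongest peaks, 21 to 25 were kept. Stricter thresholds could remove none of them, and the 21 followed from leaving out wide peaks, 4 of which were among the 25. The share of shared summits at gene boundaries was 2.54% with −log10 q of at least 5 (chance 2.12%) and 1.59% with at least 10 (chance 2.13%, below it). The difference in boundary share between shared and other peaks lost its call in replicate 1 at −1.34 (at least 5), −0.413 (at least 10) and −0.834 percentage points (q of at most 0.05), and in replicate 2 at −0.628, −1.42 and −0.651, and at −0.941 with equal numbers of peaks per list. The difference in median fold in replicate 1 was 0.213 with −log10 q of at least 10 (permutation p = 0.60). The correlation of peak density with gene density reached rho = −0.483 (at least 5) and −0.443 (at least 10), past the unadjusted threshold. The share in amplified regions, never called for shared peaks, fell below its chance level at 0.0% with −log10 q of at least 5, 0.0% with at least 10, 0.0% with q of at most 0.05, 0.150% with summits within 100 bp and 0.265% within 500 kb. With peaks of either replicate, 1 gene list, olfactory receptors, was called in place of 0. The cause of these changes was not tested, beyond the smaller number of peaks that each stricter threshold leaves.

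With each replicate alone, the share at gene boundaries was 5.83% to 6.35%, that outside genes 46.4% to 48.4%, gene lists called 0 to 0, the share in amplified regions 0.191% to 0.285% (called only without replicate 1), and the density correlation rho = −0.145 to −0.0713. No paired analysis was possible because the series has 1 ChIP group and the input has no list of its own here. The alternatives that needed a genome sequence (all motif alternatives and GC-matched backgrounds) were not run, and leaving out amplified regions gives no value for the share in those regions. In simulation a list of 36 genes was called in 3 of 20 runs with 2 members given a peak and in 20 of 20 with 3; lists of other sizes were not simulated this way.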

Other observations

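The tests on SEMA3A, on the guidance and adhesion families, on peak strength and on the background were all chosen only after the results were seen.

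Some long genes held repeated shared peaks. SEMA3A, which encodes a secreted axon guidance protein, held 8 shared summits between 84055444 and 84463380 of chromosome 7 (GRCh38), with 3.64-fold to 9.75-fold enrichment in replicate 1 and 4.72-fold to 14.6-fold in replicate 2. NEGR1, a neuronal adhesion gene, held 5. ROBO1, an axon guidance receptor, PCDH9, a protocadherin, FOXP2, a forkhead transcription factor, and LRP1B held 4 each, as did COL11A1, PTPRQ, MBD5, MGAT4C, IMMP2L, GALNTL6, NAALADL2, PDE4D, which encodes a cyclic AMP phosphodiesterase, and SDHA. Altogether 625 protein-coding genes held at least 1 shared summit and 32 held at least 3. Those 32 had a median length of 561 kb, against 24.1 kb for all protein-coding genes, and 6 of them belonged to the axon guidance and neural adhesion families tested below. SDHA stood apart, with its 4 peaks close together in a gene of 50.4 kb. Joined over gaps of up to 500 bp they formed a single stretch, 258180 to 262505 of chromosome 5 in replicate 1. Their background ran from 7.53 to 18 reads in replicate 1, so they are not separate sites like those of the long genes.

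Uniform placements argue against chance as the source of the SEMA3A cluster. The gene spans 537 kb and 0.334 of the 99 shared summits of chromosome 7 would fall in it by chance. In 10000 placements of all shared summits on their own chromosomes, the highest count in any protein-coding gene of the genome had a median of 4 and reached 8 in 2 placements (one-sided permutation p = 0.0003). Extra copies of the region raise the input as well, and with nothing else at work they would leave the fold near 1. At the 8 peaks the median lower counting bound of the fold over the caller's background was 1.71, in the replicate where it was lower. Only peaks with enough fold over this background were listed, so that bound was raised by selection. It cannot tell whether extra copies let more sites pass the caller. The lowest bound of a single peak was 0.907, and the median replicate 2 background was 3.22 reads, against 3.0 at the other shared peaks of the chromosome (permutation p = 0.95). Placement was uniform along the chromosome, so a wider stretch rich in peaks may still account for the cluster, and no biological explanation was tested.

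A hypothesis from these genes was that axon guidance and neural adhesion families carry HOMEZ peaks more often than other genes of their length. Of 151 members, 27 held a shared summit, against 17.1 for length-matched genes (permutation p = 0.013). That count includes the genes that gave rise to the hypothesis. Without those, 18 of 140 members held one against 13.2 (permutation p = 0.19), so the difference may be chance, and members such as EPHA7 with 2 peaks and EPHA5 with 3 show no more than the counts above.

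The share of shared peaks at gene boundaries was higher in the weakest band than in the strongest, but the trend did not pass a test. The share within 1000 bp of a boundary was 5.31% (31 of 584, exact binomial 95% interval 3.63 to 7.45) where q was above 0.05 in a list, and 1.59% (2 of 126, 0.193 to 5.62) where −log10 q was at least 10 in both. The share in gene bodies was 46.9% and 57.9% in the same bands. The correlation of strength with lying at a boundary was −0.0468 (two-sided permutation p = 0.07, across peaks).

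Across the 24 chromosomes, the density of shared peaks correlated with the median background at peaks by Pearson's r = 0.471 (permutation p = 0.019), and rho missed the threshold at Spearman's rho = 0.354 (permutation p = 0.09, adjusted over 2 relations 0.18). Without chromosomes 19 and Y, r was 0.521 (permutation p = 0.012) and rho 0.384 (permutation p = 0.078). Y lay farthest from the median background, but 19 was tied with chromosomes 5 and 7, each at 3.0 reads. Chromosome 5 had the highest density, and leaving out 5 or 7 in place of 19 was not tried.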
